A study of Homo sapiens with 4 samples.

How the data were processed

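RNA of HCT116 cells was measured in 4 samples, 2 transfected with control siRNA and 2 with CD44 siRNA, and samples were grouped by the sample titles. Per the labels' protocols, 25 ng of total RNA was amplified and labelled with Cy3 for one-colour arrays. The deposited scanner files hold spot intensity values on a linear scale, which per the file headers were extracted with Agilent Feature Extraction 10.5.1.1, with background subtraction and detrending and without scaling between arrays. The submitters' processing notes name Feature Extraction 9.5 instead, and which version made the deposited value table is not given in the sources used here. The deposited value table holds a linear ratio of each probe to its median over the 4 arrays: the median ratio was 1 (within 1e-04) for 100% of the 23507 probes well above background on all 4 arrays. The medians of its columns, in the order control 1, control 2, CD44 siRNA 1 and CD44 siRNA 2, were 0.941, 0.965, 0.909 and 0.914. Its scale and centring follow from the comparison with the scanner values (slopes 0.983 to 1.01), its direction by heading opposes them, and the array scaling behind it remains unknown.

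Each array had 45015 features, of which 1639 control features were left out. Log2 of the processed signal minus the log2 of the array's 75th percentile over non-control features was used, features marked as outliers were left out, and spots of a probe were averaged, which left 41000 probes, 156 of them without a value on every array. Probes well above background on both arrays of at least 1 group were tested, 24801 in all. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Residual degrees of freedom were 2 and the prior added 2.37. Replicates correlated at 0.9959 (control) and 0.9966 (CD44 siRNA) across tested probes, and arrays of different groups at 0.9847 to 0.9856, where probes are not independent replicates. The median SD was 0.068 in the control group and 0.063 in the CD44 siRNA group on the log2 scale.

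The files carry no gene names, so the accession of each probe was matched without versions to a RefSeq table of assembly GRCh38.p14, used for names only. A single symbol was found for 24794 probes (16961 symbols), several for 0 and none for 16206. Of the tested probes 7457 had no symbol, and 1880 of these were called. No coordinates are given, because the headers name build hg18. A gene was represented by its brightest tested probe. Of 3970 genes with more than 1 tested probe, 45 had probes called in both directions. Where every array of a group was not well above background, the fold is a bound, computed against the higher of the lowest signal well above background and the probe's own signal on each array of that group.

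The groups, tests, gene lists, the rule for named genes and the other settings tried were fixed before the data were examined. The rule took CD44, the 10 genes with the largest rise and the 10 with the largest fall among called genes with an official symbol that were well above background on both arrays of the higher group and whose groups did not overlap, and up to 3 called members of each list with the largest absolute change. Other list members named in the text were chosen after their values were seen, and some genes that the rule takes are not reported here. The 24 lists held 447 genes, 8 of which had no matched probe. Lists were tested with limma's camera (preset correlation 0.01) with adjustment over the lists, and compared with 10000 random lists matched on mean signal. Camera sets a list against the other genes. The fry test, used as an alternative, does not, so it can pass lists that changed no more than other genes.

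Alternatives were quantile normalization, median scaling, normexp (offset 50) with quantile normalization, the value table with columns placed by the scanner array they follow, no filter and a stricter filter on dim probes, an intensity trend with robust fitting, a 2-fold threshold, the replicate number as a block, each array left out in turn, the mean of all probes of a gene, camera with an estimated correlation, and fry. The normexp correction was to use mean spot signals, which the files used here do not hold, so median spot and background signals were used. A list was counted as reversed where its median or the direction of its test turned, a definition set after the values were seen. The value table read by its own headings, and testing without a filter but with a trend and robust fitting, were the exceptions, added after seeing the data.

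The fit was tested on simulated data for this comparison, with 24801 probes of which 200 were changed. It called 0 of 73 probes changed by 0.5 on the log2 scale, 37 of 74 changed by 1 and 50 of 53 changed by 2, with 6 false calls. With so few changed probes the adjustment is stricter than in the real arrays. A shift of 0.5 of 1 list among 12233 simulated genes was recovered, with 0 other lists called.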

Results

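Gene expression was measured in HCT116, a human colon cancer cell line, after transfection for 72 h with a control siRNA or with siRNA against CD44, the cell-surface receptor for hyaluronan. Each group held 2 samples, and each sample was hybridised to 1 one-colour oligonucleotide array after amplification from 25 ng of total RNA. Of 41000 probes, 59.8% and 66% were well above background on the control arrays and 61.3% and 59.6% on the CD44 siRNA arrays. The 75th percentiles of the processed signal were 428 and 466 in the control group and 377 and 448 in the CD44 siRNA group, and 0 features were saturated. All 4 arrays lay on 1 slide and were read in 1 scan, with the control samples at positions 1 and 2 and the CD44 siRNA samples at positions 3 and 4, so position and group cannot be told apart. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

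The series asks how the transcriptome of these cells differed between CD44 siRNA and control siRNA. CD44 itself was lower after CD44 siRNA. Its processed signal was 12800 and 12970 in the control samples and 5477 and 6753 in the CD44 siRNA samples. Relative to the 75th percentile of each array, its log2 level was 4.85 ± 0.07 (SD, n = 2) with control siRNA and 3.89 ± 0.04 (SD, n = 2) with CD44 siRNA. The log2 fold change was -0.96 (SE 0.07, 95% confidence interval -1.16 to -0.77), a 1.95-fold lower level, with a limma adjusted p of 0.00517. This value comes from the single CD44 probe (accession NM_000610), which was well above background on all 4 arrays. The deposited value table, read by its own column headings, gave the opposite sign for CD44 (log2 fold change 0.90, limma adjusted p = 0.003), because its columns followed the scanner arrays of the other group. Directions below are those of the scanner files and their labels.

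**Figure D1:**
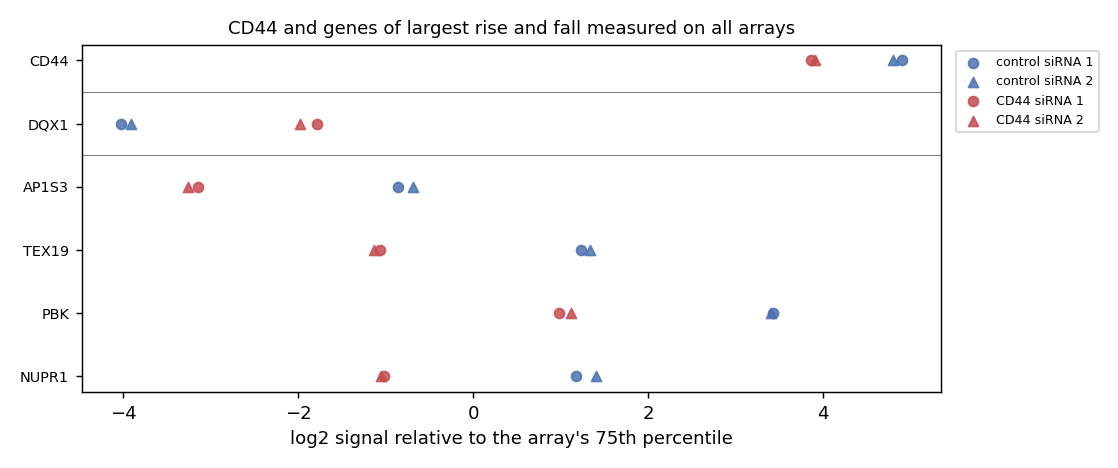
Log2 signal relative to each array's 75th percentile (horizontal axis) of CD44 and of those genes of largest rise and largest fall that were well above background on all 4 arrays, with 1 point per array, blue for control siRNA and red for CD44 siRNA. CD44 lay at 4.85 on average in the control samples and at 3.89 in the CD44 siRNA samples, and for each gene shown both arrays of one group lay on the same side of both arrays of the other.

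Expression changed broadly. Of 12233 genes tested, 2084 were higher and 1836 were lower after CD44 siRNA (limma, Benjamini-Hochberg adjusted p below 0.05), and 3764 of these 3920 genes were well above background on all 4 arrays. Most changes were small, with a median absolute log2 fold change of 0.48 among the genes called. The fitted fold was at least 2 for 141 higher and 242 lower genes, of which 115 and 193 were well above background on all 4 arrays. CD44 was not the gene that fell furthest, since 267 called genes had a larger fitted fall. Of these, 50 were not well above background on all 4 arrays, so that a larger fall than that of CD44 is not established for each of them. At the level of probes, 7311 of 24801 tested (29.5%) passed, 3719 higher and 3592 lower. The values of the groups did not overlap for 73.7% of genes, against 33.3% by chance for 2 samples against 2. The balance of directions depended on the scaling: subtracting the array median gave 4815 higher and 2735 lower probes and 2604 higher and 1325 lower genes, and the deposited value table, with its columns placed by the scanner array they follow, gave 4523 higher and 2833 lower probes. The number of calls depended on the filter and on each array: with all 40844 unflagged probes tested, limma called 0 probes and 8961 had an unadjusted p below 0.05 (10566 were called there with an intensity trend and robust fitting), and 1809, 1821, 1049 and 885 genes were called without control siRNA replicate 1, control siRNA replicate 2, CD44 siRNA replicate 1 and CD44 siRNA replicate 2.

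**Figure D2:**
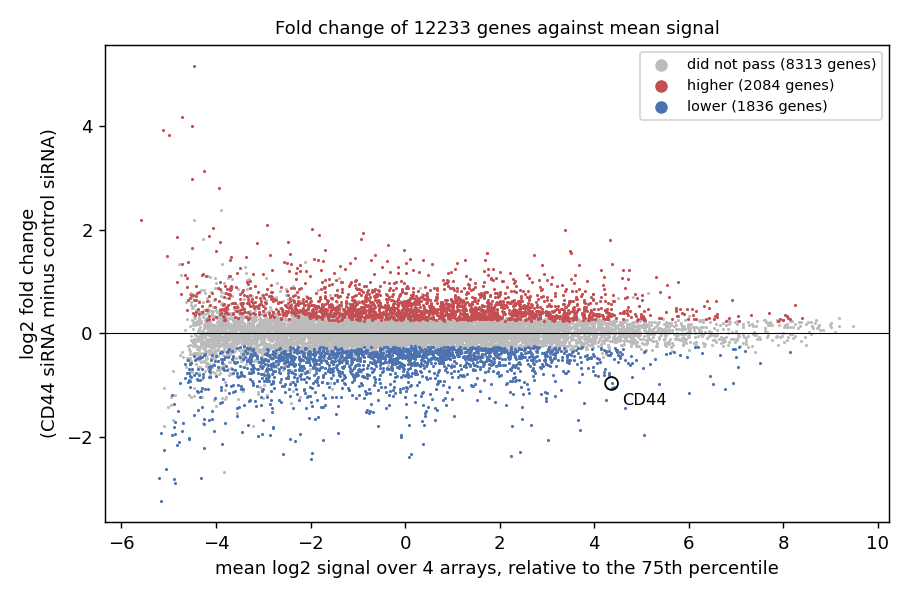
Log2 fold change, CD44 siRNA minus control siRNA (vertical axis), against the mean log2 signal over 4 arrays relative to the 75th percentile (horizontal axis), with 1 point per gene. Red points are the 2084 genes called higher, blue points the 1836 called lower, grey points did not pass, and the circle marks CD44 at -0.96.

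By fitted fold, the largest rises were mostly of genes that were not well above background in either control sample, for which only a lower bound of the fold can be given. Their rank is therefore not established, and some bounds lie below the folds of genes measured in both groups, such as CCN1 (3.97-fold). B3GAT1, a glucuronyltransferase that makes the HNK-1 carbohydrate epitope, was at least 7.43-fold higher after CD44 siRNA. ARL11 was at least 4.85-fold higher, NLRP3, the sensor protein of an inflammasome, at least 4.79-fold, and FGF1, a fibroblast growth factor, at least 4.42-fold on the brighter of its 2 probes. COL21A1 was at least 3.4-fold higher, DEFB103B at least 3.28-fold, MARCHF4 at least 3.08-fold and the adhesion molecule ICAM1 at least 1.22-fold. The probe of DEFB103B cannot be assigned with certainty, because DEFB103A is a near-identical copy. DQX1 was measured in both groups and was 4.25-fold higher (log2 fold change 2.09, SE 0.10, limma adjusted p = 0.00378). Each bound sets the mean of the brighter group against the lowest signal well above background on the arrays of the dimmer group.

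Among the largest falls, PBK, a mitotic kinase, was 5.15-fold lower, with a log2 level of 3.42 ± 0.02 (SD, n = 2) in the control samples and 1.05 ± 0.10 (SD, n = 2) in the CD44 siRNA samples. AP1S3, a subunit of a clathrin adaptor, was 5.37-fold lower, TEX19 5.23-fold and NUPR1, a stress-induced nuclear protein, 5.03-fold. These 4 genes were well above background on all 4 arrays, and limma gave each an adjusted p of 0.00373. CIB4 was at least 3.04-fold lower, XYLB at least 2.14-fold, PPP1R1B at least 2.05-fold, OAS1 at least 1.98-fold, CHRNA1 at least 1.72-fold and CALCA at least 1.64-fold, since none of these was well above background in the CD44 siRNA samples. Their place among the largest falls rests on fitted folds and is not established. Each bound lies below the fall of genes measured on all 4 arrays, such as DDIT4 (3.9-fold).

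Targets of the stress-response transcription factor ATF4 fell together. Of 20 measured genes of the ATF4 and unfolded protein response list, 13 were lower, 0 were higher and 7 did not pass (14 lower when adjusted over the list alone), with a median log2 fold change of -0.63. DDIT4, an inhibitor of mTORC1 signalling, fell by 1.96 on the log2 scale, PSAT1, an enzyme of serine synthesis, by 1.86, and DDIT3, which encodes the transcription factor CHOP, by 1.52. ASNS, asparagine synthetase, fell by 1.07 and ATF4 itself by 0.56. HERPUD1, a gene of the endoplasmic reticulum, fell by 0.48, and among the members that did not pass were HSPA5 (0.09), HSP90B1 (-0.02), PDIA4 (0.22) and ATF3 (0.14). The list stood apart from the other genes by limma's camera test (adjusted p = 2.09e-05 over 24 lists), though not with an estimated correlation between genes (adjusted p = 0.63 with an estimated correlation). The estimate was -0.0061 for this list, below the preset 0.01, so a larger correlation was not what lost the call. With an estimate, camera also drops to the 2 residual degrees of freedom of the fit, here and for the lists below. On so few, only a very large test statistic could pass over 24 lists, so a lost call says little about correlation.

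Targets of the tumour suppressor p53 rose. Of 23 measured genes, 17 were higher, 2 were lower and 4 did not pass (17 and 2 also when adjusted over the list alone), with a median log2 fold change of 0.64 (0.4115 with normexp). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.95-fold (log2 fold change 1.56, SE 0.07, limma adjusted p = 0.00373), with 1.77 on its other probe. BTG2 rose 1.96-fold and MDM2, the ubiquitin ligase of p53, had a log2 fold change of 0.89. The control level of MDM2 was -5.05, the lowest of the measured members and close to background, so the size of its change is uncertain. BAX, a pro-apoptotic protein, rose 2.18-fold on its brighter probe while its other probe had a log2 fold change of 0.05. The 2 members that fell were GDF15 (-0.96) and SESN2 (-0.69), and SESN2 also belongs to the ATF4 list. Limma's camera test gave an adjusted p of 0.000121, and the adjusted p = 0.63 with an estimated correlation, which was 0.046. That test had 2 residual degrees of freedom as well, so the loss does not show an effect of the correlation.

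Targets of the transcriptional regulators YAP and TEAD rose as well. Of 13 measured genes, 10 were higher, 0 were lower and 3 did not pass (12 higher when adjusted over the list alone), with a median log2 fold change of 0.71. CCN1, a secreted matricellular protein, rose 3.97-fold (log2 fold change 1.99, SE 0.07, limma adjusted p = 0.00373), and its 3 probes lay between 1.98 and 2.09. CRIM1 rose 1.98-fold and CCN2 had a log2 fold change of 0.93. LATS2, a kinase of the Hippo pathway, rose 1.97-fold on its brighter probe, while its other probe had a log2 fold change of 0.11. Limma's camera test gave an adjusted p of 0.000121, and the adjusted p = 0.63 with an estimated correlation, which was 0.043. As for the p53 list, the 2 residual degrees of freedom of that test keep the loss from showing an effect of correlation.

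Interferon response genes fell. Of 18 measured genes, 11 were lower, 1 was higher (IRF7, log2 fold change 0.45) and 6 did not pass (15 lower and 1 higher when adjusted over the list alone), with a median of -0.48 that was the same with 2 genes at their bound. Besides OAS1, IFI44 fell by 1.30 on the log2 scale and IFI6 by 1.11. Limma's camera test gave an adjusted p of 0.000121, and the adjusted p = 0.76 with an estimated correlation, which was 0.51. The fry test of limma, which asks whether the genes of the list moved on balance one way, did not pass for this list (adjusted p = 0.0535).

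Mitotic genes were lower by small amounts. Of 23 measured genes, 11 were lower, 0 were higher and 12 did not pass (13 lower when adjusted over the list alone), with a median log2 fold change of -0.26. CENPE, a kinetochore motor protein, fell by 0.62 on the log2 scale, CDC25C, a phosphatase that activates CDK1, by 0.51, and CCNB1, cyclin B1, by 0.42. Limma's camera test gave the list an adjusted p of 0.000148, and the adjusted p = 0.73 with an estimated correlation, which was 0.19. Genes of DNA replication were mixed, with 4 higher and 7 lower of 26 (5 and 10 when adjusted over the list alone), and the list did not pass by limma's camera test (adjusted p = 0.0625), although it did with quantile normalization (adjusted p = 0.0349), with normexp (0.015), without a filter (0.0318), without control siRNA replicate 1 (0.0323), with the mean of all probes (0.0338), and by fry (0.0395). MCM6, a subunit of the replicative helicase, fell by 1.08 and RFC3 by 1.05. E2F1 had a log2 fold change of 0.66.

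**Figure D3:**
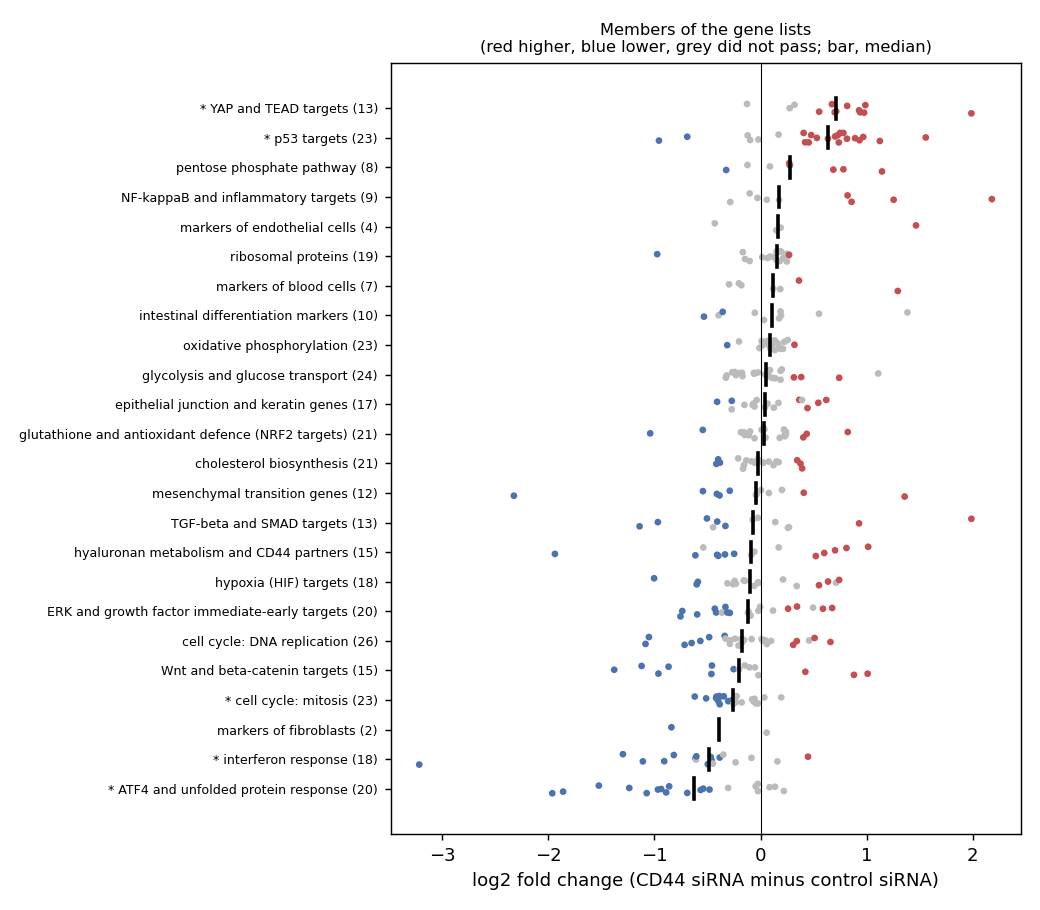
Log2 fold changes, CD44 siRNA minus control siRNA (horizontal axis), of the measured members of 24 gene lists (rows, with the number of genes in parentheses), where each point is a gene and each bar the median. Asterisks mark the 5 lists with a camera adjusted p below 0.05, with medians of 0.71 (YAP and TEAD targets), 0.64 (p53 targets), -0.26 (mitosis), -0.48 (interferon response) and -0.63 (ATF4 and unfolded protein response). These calls use the preset correlation. Camera with an estimated correlation, which has 2 residual degrees of freedom, called 0 of the 24 lists.

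Some genes related to CD44 and to metabolism changed, in both directions except in glycolysis, and their lists did not pass limma's camera test. Among hyaluronan metabolism genes and CD44 partners, 5 were higher and 6 lower of 15 (5 and 6 also when adjusted over the list alone; camera adjusted p = 0.666). SPP1, the CD44 ligand osteopontin, fell by 1.94 on the log2 scale, and NF2, which encodes merlin, rose 2.02-fold with all 4 probes higher. The splicing regulator ESRP2 rose 1.75-fold, while ESRP1 of the same list had a log2 fold change of -0.41. In glycolysis and glucose transport 3 of 24 genes were higher and 0 lower (2 and 0 when adjusted over the list alone; camera adjusted p = 0.935), namely the glucose transporter SLC2A1 (1.67-fold), the lactate transporter SLC16A3 (1.31-fold) and PFKM (1.24-fold), and the median of 0.06 turned to -0.02 with quantile normalization. In the pentose phosphate pathway 5 genes were higher and 1 lower of 8 (5 and 1 also when adjusted over the list alone; camera adjusted p = 0.131), led by RPIA (2.21-fold), TIGAR (1.72-fold, and 0.12 on the log2 scale on its other probe) and PGD (1.61-fold). Fry passed this list upward (adjusted p = 0.0326), and TIGAR also belongs to the p53 list. Among genes of glutathione and antioxidant defence 3 were higher and 2 lower of 21 (3 and 2 also when adjusted over the list alone; camera adjusted p = 0.693). NQO1 fell by 1.04, the cystine transporter SLC7A11 fell by 0.54, and haem oxygenase HMOX1 rose 1.77-fold. In oxidative phosphorylation 1 gene was higher (NDUFB3, 1.25-fold) and 1 lower (ATP5MC1, 1.24-fold) of 23, with 0 and 0 when adjusted over the list alone (camera adjusted p = 0.232).

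The target lists in this paragraph did not pass limma's camera test. Of 15 Wnt and beta-catenin targets, 3 were higher and 7 lower (3 and 7 also when adjusted over the list alone; camera adjusted p = 0.0858). RNF43, a negative regulator of Wnt receptors, fell by 1.38 on the log2 scale and SOX4 by 1.12, while CCND1, cyclin D1, rose 2.01-fold, and CD44 itself is a member of this list. Of 9 NF-kappaB targets 4 were higher and 0 lower (4 and 0 also when adjusted over the list alone; camera adjusted p = 0.137), with TNFAIP3 2.39-fold and RELB 1.81-fold higher besides ICAM1. Of 20 ERK and growth factor targets 4 were higher and 8 lower (4 and 8 also when adjusted over the list alone; camera adjusted p = 0.232), with ETV5 lower by 1.69-fold, SPRY4 lower by 1.67-fold and FOSL1 higher by 1.6-fold. Of 13 TGF-beta and SMAD targets 2 were higher and 5 lower (3 and 6 when adjusted over the list alone; camera adjusted p = 0.466), where ID1 fell by 1.14 and ID3 by 0.97. The 2 called higher, CCN1 and CCN2, were both shared with the YAP list. Of 18 hypoxia targets 3 were higher and 3 lower (3 and 3 also when adjusted over the list alone; camera adjusted p = 0.564), with BNIP3L 2-fold lower and INSIG2 1.55-fold higher. Cholesterol biosynthesis had 3 higher and 3 lower of 21 (3 and 3 also when adjusted over the list alone; camera adjusted p = 0.663), among them MSMO1 (-0.42), INSIG1 (-0.40) and LSS (0.39).

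Epithelial and mesenchymal genes did not move as groups. Of 17 epithelial junction and keratin genes 4 were higher and 2 lower (5 and 3 when adjusted over the list alone; camera adjusted p = 0.781), with KRT8 rising 1.54-fold, KRT19 1.46-fold and TJP1 1.36-fold. Of 12 mesenchymal transition genes 2 were higher and 5 lower (2 and 5 also when adjusted over the list alone; camera adjusted p = 0.39), where the matrix protein SPARC fell by 2.33 on the log2 scale, vimentin (VIM) by 0.54 and ACTA2 rose 2.57-fold. Of 10 intestinal differentiation markers 0 were higher and 2 lower (0 and 2 also when adjusted over the list alone; camera adjusted p = 0.919), namely CA2 (-0.53) and KLF4 (-0.36), and the median of 0.10 lay above 0 while the camera direction was down. Among 19 ribosomal protein genes 1 was lower and 1, RPL32, was higher (0 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.294). Markers of other cell types gave 2 of 7 blood cell genes higher (CD68 2.45-fold and CSF1R 1.29-fold; 2 and 0 when adjusted over the list alone; camera adjusted p = 0.661), 1 of 2 fibroblast genes lower (FBLN1, -0.84; 0 and 1 when adjusted over the list alone; camera adjusted p = 0.418) and 1 of 4 endothelial genes higher (ROBO4, 2.76-fold; 1 and 1 when adjusted over the list alone; camera adjusted p = 0.564). On their other probe the log2 fold change was 0.3684 for ROBO4, -0.3627 for FBLN1, 0.2961 for INSIG2 and 0.9713 for TJP1, and the lowest of the 4 probes of LSS gave 0.1153. ATP5MC1, CDC25C, KLF4 and INSIG1 lost their call when the array median was subtracted, and PFKM and RPL32 when the arrays were quantile normalized. With an estimated correlation, camera of limma called 0 of the 24 lists, 1 had an unadjusted p below 0.05, and fry called 12. Lists that passed by fry and not by camera, besides DNA replication, were the pentose phosphate pathway (adjusted p = 0.0326), Wnt (0.0356), NF-kappaB (0.02) and ERK targets (0.0395), and markers of blood cells (0.0388), fibroblasts (0.0395) and endothelial cells (0.0356). Because 3920 of 12233 genes were called, a pass by fry alone does not show that a list stood apart from the other genes.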

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

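The tests in this part were chosen after the result was seen. The deposited value table stands out because its columns follow scanner arrays of the other group. Across 23507 probes, the column headed control siRNA 1 correlated at 0.99601 with the scanner array labelled CD44 siRNA 1, control siRNA 2 at 0.99633 with CD44 siRNA 2, CD44 siRNA 1 at 0.99625 with control siRNA 1 and CD44 siRNA 2 at 0.99636 with control siRNA 2, while correlations with the array of the same heading lay between -0.754 and -0.738. By heading, the ratios of CD44 were 0.671 and 0.735 in the control columns and 1.36 and 1.26 in the CD44 siRNA columns. Ratios turned upside down would bring every own-heading correlation near the opposite extreme, and the lowest was -0.754, which argues against that. Scanner files exchanged between the groups would leave CD44 raised by its own siRNA in the scanner files, where the interval of its log2 fold change ended at -0.77, below 0. An exchange of the column headings stays open, because the match it needs is the one that drew attention to the table. Taking the scanner labels as right takes for granted that the siRNA lowered its target, and no record of the sample handling was analysed here.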

How the results depend on the processing

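The value table by its own headings and the unfiltered fit with a trend were chosen after seeing the data. CD44 stayed lower and past the threshold under the scalings, stricter filter, trend and block (log2 fold change -1.04 to -0.89), and with each array left out (-1.01 to -0.91, limma adjusted p 0.0249 to 0.0382). It lost the threshold without a filter (-0.96, limma adjusted p = 0.0777, range over its alternatives 4.59e-43 to 0.0777) and turned to 0.90 in the value table by its own headings, which has 1370 genes higher. Without a filter limma called 0 probes and 0 genes, 0 in each direction, with 8961 of 40844 probes at an unadjusted p below 0.05, a prior of 1.33 degrees of freedom and a lowest adjusted p of 0.0769; a trend and robust fitting there, with a prior of 612 degrees of freedom and so a variance almost wholly pooled over probes, called 10566 probes (5629 higher) and 5656 genes, 3719 of them among the 3920. The 2-fold threshold left 759 probes (266 higher, 493 lower) and 383 genes (141 and 242 by fitted fold) by construction. With the replicate number as a block, 4083 probes (1959 and 2124) and 2150 genes (1094 and 1056) passed. The block leaves fewer residual degrees of freedom than the 2 of the main fit. Same-numbered samples did not deviate together (r = -0.038 across probes). With a single pair of differences over probes that are not independent, a shared culture or batch is not excluded. Leaving out 1 array, which leaves a lone sample assumed to vary like the other group, gave 1729 to 3561 probes (739 to 1755 higher, 990 to 1885 lower), 885 to 1821 genes (391 to 932 higher, 494 to 935 lower) and 5 to 6 lists. Of 80 genes taken by the naming rule, 80 lost the threshold without a filter, 10 with the block, 4 with median scaling, 4 in the value table, 2 with quantile normalization, 1 with normexp, and 15, 13, 26 and 27 without control 1, control 2, CD44 siRNA 1 and CD44 siRNA 2; 0 turned direction in the settings run for single genes, which leave out the value table by its own headings, where 3416 genes also called in the main fit had the opposite sign. The DNA replication list gained a call with quantile normalization, normexp, no filter, the mean of probes and without control 1 (adjusted p 0.015 to 0.0349). The 5 called lists kept their call and direction in 11 of 11 refits each, leaving out the trend, which does not enter camera, and median scaling, which moves all genes alike; camera with an estimated correlation called 0 lists (1 at an unadjusted p below 0.05), and fry called 12 but not the interferon list (adjusted p = 0.0535). Lists that turned, none of them called by camera, were glycolysis (-0.0153 with quantile normalization, -0.0268 with normexp, 0.0427 with the stricter filter, 0.0361 with the mean of probes, -0.0489 to 0.119 with an array left out), epithelial genes (-0.0070 with quantile normalization, -0.0465 to 0.114 with an array left out), intestinal markers (0.144 with quantile normalization, 0.0715 with normexp, 0.104 with the block, 0.0361 to 0.13 with an array left out), hypoxia (-0.255 to 0.0702 with an array left out), glutathione (-0.0014 with quantile normalization), mesenchymal genes (0.0362 with median scaling, 0.0239 in the value table, 0.0051 without a filter), cholesterol (0.0534 and 0.0406 with median scaling and the value table), TGF-beta (0.0038 with median scaling), fibroblast markers (0.136 without a filter) and hyaluronan genes (-0.0883, direction of fry). The cause was not tested for these, except that median scaling moves all genes alike, so medians near 0 turn with it by construction. The slide could not be a block, since all 4 arrays shared 1. Signal over background limits folds of dim genes to bounds.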

Other observations

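The 5 gene lists first used in this part, and the tests of dim probes and of ER chaperones, were chosen after the results were seen. Genes of amino acid transport and of serine and one-carbon synthesis fell together: 10 of 16 were lower, 0 higher and 6 did not pass (13 lower when adjusted over the list alone), with a median log2 fold change of -0.44 (limma camera adjusted p = 4.11e-06 over 5 lists; adjusted p = 0.17 with an estimated correlation). GPT2, an aminotransferase, fell by 1.12, the neutral amino acid transporter SLC1A4 by 0.91, SLC43A1 by 0.76 and SHMT1, serine hydroxymethyltransferase, by 0.68. Of 19 cytosolic aminoacyl-tRNA synthetases 7 were lower and 3 higher (9 and 3 when adjusted over the list alone), with GARS1 at -0.70, AARS1 at -0.64 and KARS1 at 0.44. Of 30 focal adhesion and actin genes 6 were higher and 10 lower (7 and 10 when adjusted over the list alone), among them CAV2 (1.51), the adaptor paxillin (PXN, 1.33) and CAV1 (0.77), and the integrin ITGA2 (-0.81).

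A hypothesis is that ATF4 activity was lower after CD44 siRNA. The list of amino acid transport and serine and one-carbon synthesis had a median of -0.44 and passed camera. It did not pass with an estimated correlation, which was -0.04, on 2 residual degrees of freedom (camera adjusted p = 0.17). It goes in the direction of the hypothesis, although SLC7A11 is shared with the antioxidant list and these genes overlap in function with those that prompted the test. The aminoacyl-tRNA synthetases had a median of -0.17 and did not pass (limma camera adjusted p = 0.14), which leaves them open. A lower unfolded protein response as a whole stays open too, with ER chaperones and folding enzymes at a median of -0.0270 and 3 lower and 1 higher of 15 (3 and 1 when adjusted over the list alone; limma camera adjusted p = 0.38).

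Lower interferon signalling, and altered adhesion and actin cytoskeleton as the background of the YAP and TEAD targets, were tested in the same way and stay open. Genes of MHC class I and antigen processing had a median of -0.0025, with 3 higher and 1 lower of 14 (3 and 4 when adjusted over the list alone; limma camera adjusted p = 0.82), and focal adhesion and actin genes a median of -0.0045 (limma camera adjusted p = 0.82). Fry passed both lists upward (adjusted p = 0.00374 for MHC class I and 0.0153 for focal adhesion), while the camera direction was down for both. For MHC class I an upward shift is opposite to lower interferon signalling. A focal adhesion median without a rise was set beforehand to count against altered adhesion, and -0.0045 met this by a small margin. Both lists hold members that moved each way, so their medians decide nothing.

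By fitted fold 267 genes fell further than CD44 itself, and the 50 not well above background on all 4 arrays are left aside here. Noise of dim probes that differs between replicates is argued against: replicates of a group differed by more than the CD44 fold in at most 64 of the tested genes in either direction, below the count of the remaining genes (exact 95% interval 189 to 248). Noise shared by the arrays of a group is not covered by this. The interval also treats genes on the same arrays as independent, which they are not. A floor or ceiling of the CD44 probe is argued against: the probe was unsaturated and above background on all 4 arrays, and 9 genes at least as bright as CD44 in the control arrays fell further, among them ASNS, DDIT4, FOXC1, ID1, PCK2, PCLAF, PLAU and TRIB3. Effects of the siRNA on other transcripts, and effects that follow from lower CD44, may both contribute and cannot be told apart with 1 CD44 siRNA group. The samples include no untransfected or mock-transfected cells. An effect of the control siRNA, in any gene or list including the interferon response, therefore cannot be told apart either. Sequences of siRNAs and transcripts were not analysed here.

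The shift of 5 gene lists was set against 2 technical explanations. A trend with probe brightness is argued against, since 5 of the 5 medians lay outside the central 95% of 10000 random lists matched on mean signal. Array scaling is argued against, since with quantile normalization and normexp, which move genes by different amounts, the 5 lists kept their sign and passed camera (highest adjusted p = 0.000187), the medians being at least 0.2546 in absolute size, though that of the p53 targets went from 0.6356 to 0.4115 with normexp. Median scaling moves all genes alike and tests nothing here. The position on the slide follows the group and stays open, as does the spread between cultures. With an estimated correlation between genes, on 2 residual degrees of freedom, the lowest adjusted p of camera was 0.63. A biological response to CD44 siRNA is therefore untested beyond these samples.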
